A study of Mus musculus with 5 samples.

How the data were processed

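RNA-seq values were used for 5 libraries of wild-type mouse brain, 1 of OPCs, 1 of astrocytes and 3 of cortex. Per the labels' protocols, RNA was isolated with Trizol and libraries were made with an Illumina RNA-seq kit. The labels do not say how the cells were obtained or whether they were cultured. Per the submitters' processing notes, TopHat, Cufflinks and Cuffdiff were used with the mouse genome build mm9, with no versions in the sources used here. The deposited values are FPKM with lower and upper confidence bounds, per the file headers, which have the layout of Cufflinks gene tracking tables. Starting positions in the files were 0-based and were raised by 1, since for 1052 of 1099 microRNA genes the span matched the length only on that reading.

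The files differed in how they were made. The OPC and astrocyte files held 35376 and 32052 loci, of which 11803 and 8440 were assembled loci without a gene name. They joined the names of some neighbouring genes, at 631 and 594 loci. Each cortex file held 24460 annotated loci with no unnamed or joined ones. This difference coincides with the difference between cells and tissue. Genes were matched by symbol, which gave 22671 genes by exact symbol and 148 more, Pdgfra among them, where a joined name held 1 gene and small RNA genes only. For those 148, a joined locus in at least 1 cell file was set against the gene alone in cortex. Only 139 joined loci in OPCs and 136 in astrocytes were of this kind. The other joined loci were left out, and with them any gene that no other locus named. Several loci of 1 symbol were summed, which affected 37 tested genes. After the files had been inspected, values whose status was a failed estimate were treated as missing, which removed 2 genes. Of the 22819 genes in all files, 13934 with at least 1 FPKM in at least 1 library were tested, and 13323 of their symbols were found in the reference gene table. Of the tested genes, 970 were listed at 0 in at least 1 library.

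Depth is unknown as counts. From the widths of the confidence bounds of 9598 genes, assuming that these widths reflect counting error alone, the depth relative to cortex replicate 1 was estimated as 0.685 for OPCs, 0.758 for astrocytes, 0.365 for cortex replicate 2 and 0.394 for replicate 3. The FPKM lay outside its own bounds for 17.5% of loci in OPCs, 14.7% in astrocytes and 11.3%, 4.90% and 5.18% in cortex. Apart from this rough estimate of depth, the bounds were therefore used only in 1 alternative.

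Values were analysed as log2 of FPKM plus 1. A model with 3 groups was fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with a trend), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a log2 difference of at least 1. The lone OPC and astrocyte libraries were assumed to vary as the cortex libraries do. Between OPCs and astrocytes, no test was made and a gene stood apart at a log2 difference of at least 2. A test of the OPC comparison was run on simulated data with 13934 genes. It recovered 95.6% of genes changed by 1.5 on the log2 scale, 98.5% of those changed by 2 and 98.5% of those changed by 3. It called 3 of 13734 unchanged genes. The simulated OPC library was given the spread of the cortex libraries, so the test does not check the assumption above. It changed 200 genes, drawn only from those above a minimum level in cortex, whereas 6120 were called in the data. The recovery therefore does not cover genes that are low in cortex. Gene lists for cell types and pathways were described by the median of their tested genes, by its percentile among 10000 random lists of the same size matched on mean expression, and by the number of genes called over all genes and over the list alone.

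The groups, comparisons, tests, gene lists and the first set of alternatives were fixed before the data were examined. So was the rule for naming genes. It takes a panel of 14 glial and neuronal genes in each comparison. It adds the 6 genes with the largest difference in each direction among those called, at 10 FPKM or more on the higher side and with an ordinary gene symbol. For each list it takes the pair of genes with the largest difference, the pair with the highest level, and called genes that go against the majority. Some genes that the rule names are not reported here.

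The alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, scaling to a fixed sum, quantile normalization and upper quartile scaling, eBayes without the trend, limma's treat, a rule with no test, other size rules, leaving out each cortex library, the highest locus per symbol, and confidence bounds that do not meet. Those chosen after seeing the data kept exact symbols only, left out small RNA genes, kept only genes with the same coordinates in all files, left out genes listed at 0, required a normal status, or kept failed estimates at 0. Copies of ribosomal protein genes were counted with blastn 2.17.0+ against reference pseudogenes, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.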

Results

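RNA was sequenced from wild-type mouse brain of a mixed background, as 1 library of oligodendrocyte progenitor cells (OPCs), 1 library of astrocytes and 3 libraries of cortex. OPCs are the dividing precursors of the myelin-forming oligodendrocytes, and astrocytes are the glia that take up transmitter and support neurons. The series concerns gliomas induced with a retrovirus carrying PDGFB, and these normal samples give the reference levels for cell types from which such tumours have been proposed to arise. The tumour libraries were not analysed here. Levels are FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library, and the read depth of each library is unknown. At least 1 FPKM was listed for 11348 of the 13934 tested genes in OPCs, for 11652 in astrocytes and for 12700, 12595 and 12639 in cortex replicates 1 to 3. The OPC and astrocyte groups had no replicates, so their values carry no error of their own, and errors on cortex values are SDs over 3 libraries.

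The 3 cortex libraries gave the spread against which the cells were judged. The median SD of a gene across them was 0.09 on the log2 scale, and 98.2% of tested genes had an SD under 0.5. Pearson's r between pairs of cortex libraries, computed across genes, which are not independent replicates, was 0.936 at the lowest. It was 0.990 at the lowest without the 268 small RNA genes. In cortex Rbfox3, which encodes the neuronal nuclear antigen NeuN, was at 75.9 ± 1.66 FPKM, and Slc17a7 at 439.6 ± 22.2 FPKM encodes the vesicular glutamate transporter of cortical excitatory neurons. Olig2 was at 18.9 ± 1.81 FPKM and Pdgfra at 20.4 ± 1.71 FPKM. Xist, chosen after its values were seen, was at 33.1 FPKM in cortex replicate 1 and at 0.149 and 0.245 in replicates 2 and 3, so replicate 1 was not from the same animal as the others. The labels do not say whether replicates 2 and 3 came from separate animals, and the p-values measure only the spread between these libraries.

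The OPC library was compared with cortex to show what sets a progenitor population apart from whole tissue. Fold values here and below are ratios of FPKM as listed, without the 1 added before taking logs. Pdgfra, the receptor for PDGF that marks OPCs, stood at 413 FPKM against 20.4 ± 1.71 FPKM in cortex, 20.2-fold higher. Olig2, a transcription factor of the oligodendrocyte lineage, stood at 366 FPKM, 19.3-fold higher than in cortex, and its neighbour Olig1 at 1101 FPKM, 13.8-fold higher. Sox10, which drives the same lineage, was 17.2-fold higher at 277 FPKM, and Cspg4, which encodes the NG2 proteoglycan, was 8.14-fold higher at 38.3 FPKM. The neuronal gene Rbfox3 was listed at 0.554 FPKM, 137-fold below cortex.

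In mm9 coordinates, Pdgfra lies on chromosome 5 from 75548316 to 75594229, in a locus that the OPC and astrocyte files list together with a small RNA gene. The cortex files hold no joined loci, so its differences from cortex set a joined locus against the gene alone. How much the small RNA gene adds was not measured. The same limit applies to H19 and to the other genes below that share a locus with small RNA genes. Olig2 lies on chromosome 16 from 91225795 to 91228922, Sox10 on chromosome 15 from 78985343 to 78994920 and Egfr on chromosome 11 from 16652206 to 16813910.

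**Figure D1:**
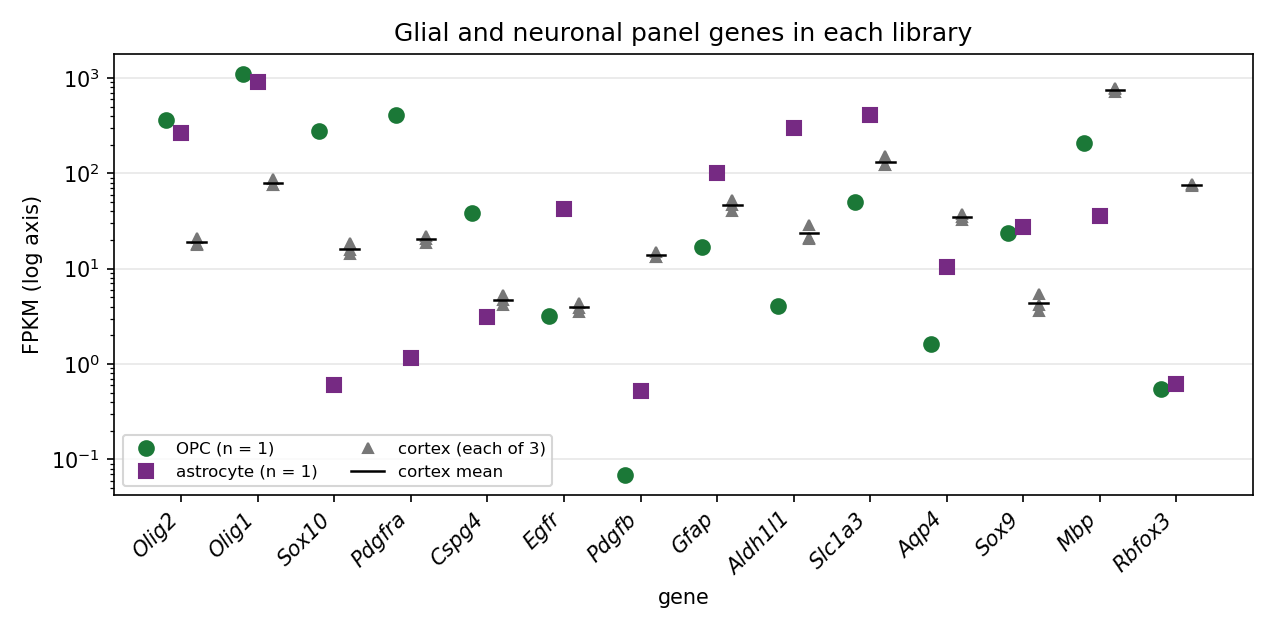
FPKM on a log axis of 14 panel genes in the OPC library (circle), the astrocyte library (square) and each of the 3 cortex libraries (triangles, with a bar at their mean). Olig1 and Olig2 lie above cortex in both cell types, whereas Sox10 and Pdgfra lie above cortex in OPCs and below it in astrocytes.

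In all, 6120 of 13934 tested genes were called in OPCs against cortex, 2936 higher and 3184 lower, with limma at a Benjamini-Hochberg adjusted p under 0.05 and a log2 difference of at least 1. Which direction held more genes depended on the setting, since quantile normalization gave 3093 higher and 2723 lower. The median log2 difference of all tested genes was 0.12. Of the lower calls 443 were for genes listed at 0 in OPCs, and the lower count of each list below includes 1 such gene at most. A listed 0 was not taken to show that a gene was unexpressed. For Pdgfra the log2 difference was 4.28 with a standard error of 0.11, and for Olig2 it was 4.21 with a standard error of 0.12. The limma tests gave Benjamini-Hochberg adjusted p-values of 1.12e-04 for Pdgfra and 1.28e-04 for Olig2, each higher than in 3 of 3 cortex libraries. The genes that rose most were H19, an imprinted noncoding RNA that shares its locus with a microRNA, at a log2 difference of 6.33, and the cell cycle genes Cenpa at 6.13, Ccnb1 at 5.50, Top2a at 5.49, Rrm2 at 5.19 and Mki67 at 5.13. Those that fell most were neuronal, with log2 differences of -8.32 for Stmn2, -8.24 for Slc17a7, -7.97 for Sst, -7.96 for Nrgn and -7.91 for Thy1. Tuba4a, a tubulin gene with near-identical relatives, was listed at 0 in OPCs and at 227, 228 and 213 FPKM in cortex.

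Of the 20 tested genes of the OPC list, 16 rose, with a median log2 difference of 2.37. The only lower call was for Lims2, listed at 0 in both cell files and at 8.80, 7.16 and 7.0 FPKM in cortex, and no fall is claimed from that 0. The mature oligodendrocyte list went the other way, with 10 of 19 genes lower and 2 higher and a median of -1.07. The myelin gene Mbp was at 208 FPKM against 756 ± 37.7 FPKM in cortex, a log2 difference of -1.85, and Mobp fell by 4.21. Mog, another myelin gene, was listed at 0 in OPCs and at 19.3, 23.1 and 18.3 FPKM in cortex. Myrf, which switches on myelin genes, and Gal3st1, which makes sulfatide, rose by 1.17 and 1.24, calls that ended when each library was rescaled to a fixed sum (0.93 and 0.98).

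Astrocyte genes were low in OPCs. Of 20 tested members 18 fell and 1 rose, with a median of -1.93. Aldh1l1, a folate enzyme typical of astrocytes, fell to 4.06 FPKM from 23.4 ± 4.77, and Slc1a3, a glutamate transporter, to 50.2 from 132 ± 16.8. The gap junction gene Gja1 had a log2 difference of -4.90, the glutamate transporter Slc1a2 of -4.80, the water channel Aqp4 of -3.78 and the filament gene Gfap of -1.39. Glul, which converts glutamate to glutamine and shares its locus with a small RNA gene, fell by 2.62, and Aldoc fell by 1.65. Sox9, a transcription factor of glial precursors as well as astrocytes, rose by 2.20. On the reactive astrocyte list 3 of 19 genes rose and 5 fell, with a median of -0.38 that became 0.21 under quantile normalization. The risers were the intermediate filament genes Vim, at 1020.1 FPKM against 32.4 ± 2.02, and Nes, at 53.8 against 4.10 ± 0.661, and the protease inhibitor Timp1.

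Neuronal, microglial and endothelial genes were lower as groups. All 20 synaptic vesicle genes fell, with a median of -3.67, led by Slc17a7 and the calcium sensor Syt1 at -7.24, and the abundant Syp and Vamp2 fell by 4.99 and 3.82. The pan-neuronal list had 19 of 20 genes lower (median -4.01), the excitatory list 14 of 15 (median -3.81) and the inhibitory list 14 of 15 (median -3.32, with the peptide genes Sst and Cck at 0.191 and 0.233 FPKM). Uchl1 was still at 160.4 FPKM after a fall of 1.48, and Map2, at 173 FPKM against 153 ± 6.13, was not called. Among glutamate and GABA receptors 14 of 19 fell (median -2.73), including Gria1 at -4.91, while the AMPA receptor gene Gria2 was at 142 FPKM against 80.1 ± 10.4 and was not called. Of 18 microglial genes 17 fell (median -3.27), with Csf1r at 0.154 and C1qc at 0.400 FPKM. All 15 endothelial genes fell (median -2.61), with Cldn5 at -5.21. Pericyte genes fell in 8 of 11 cases (median -1.91), with Rgs5 at -5.12 and Vtn at -4.22, and fibroblast genes in 13 of 14 (median -2.05), with Igf2 at -3.31 and Fn1 at -3.29. On the ependymal list 1 of 3 tested genes fell, Rsph1 at -1.30, or an uncalled -0.73 under quantile normalization (median -0.71), and the only tested red blood cell gene, Hbb-bt, which has near-identical relatives, fell by 1.56.

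Cell cycle genes formed the group with the highest median, 4.44, and 22 of 23 rose. Pcna, the sliding clamp of DNA replication, stood at 419 FPKM against 33.4 ± 2.78, and Top2a, the mitotic topoisomerase, at 161 against 2.59 ± 0.141. Ribosomal protein genes rose in 23 of 24 cases (median 1.98), including Rpl27 at 2.40 and Rpl32 at 2.35, although reads of this family can be shared with many near-identical pseudogenes. The most abundant, Rplp1, had a log2 difference of 0.996 and was called only without cortex replicate 1 (1.16), and the call for Rps2, at 1.15, ended under scaling to a fixed sum (0.84), under quantile normalization (0.31), and without cortex replicate 2 (1.10). Cholesterol synthesis genes rose in 15 of 18 cases (median 1.71), including the cyclase Lss at 3.35, Fdps at 2.91 and Idi1 at 2.62. Neural stem cell genes rose in 8 of 17 cases and fell in 1 (median 1.12), with the phosphatase Ptprz1 at 348 FPKM and Hes1, a Notch target, down by 1.26.

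Growth factor signalling genes were mixed. On the PDGF and EGF receptor list 3 of 15 genes rose and 4 fell (median -0.22, or 0.12 under quantile normalization), the risers being Pdgfra, the EGF family ligand Tgfa at 2.37 and the receptor Erbb4 at 1.67. Pdgfb, the ligand used to induce the gliomas of the series, was at 0.0690 FPKM against 13.8 ± 0.882, and Egfr at 3.21 against 3.92 ± 0.452 FPKM was not called (limma, Benjamini-Hochberg adjusted p = 0.190). Of 15 output genes of receptor tyrosine kinase signalling 8 rose and 2 fell (median 1.21), with Ccnd1 at 3.60, Myc at 3.55 and Etv5 at 1.51, and with the phosphatases Dusp6 at -1.05 and Dusp5 at -1.18. The Dusp5 call ended without cortex replicate 2 (-1.07) or 3 (-1.10), and under quantile normalization (-0.62). In the Notch list 6 of 15 rose and 4 fell (median -0.16, or 0.22 under quantile normalization and 0.45 with exact symbols only, a setting chosen after the data were seen), with the ligands Dll3 at 4.49 and Dll1 at 3.18 and the receptor Notch1 at 2.70 higher, and Notch3 at -2.0, Jag2 at -1.85, Nrarp at -1.87 and Hes1 lower.

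Immediate early genes fell in 11 of 17 cases and rose in 2 (median -1.95), Egr4 and Egr3 at -4.23 and -3.78, with Jun at 1.42 and Btg2 at 1.33 higher, the latter not called without cortex replicate 2 (1.42) or after rescaling to a fixed sum (1.12). Matrix and adhesion genes fell in 9 of 19 cases and rose in 5, with Sparc at -3.01, Col4a2 at -3.38 and Itgb1 at 1.74, and their median of -0.99 turned to 0.17 when only genes with the same coordinates in all files were kept. Lgals1 at 2.43, Fbln1 at 1.89 and Tnc at 1.12 also rose, the last not called after rescaling to a fixed sum (0.89) or under upper quartile scaling (0.997). Glycolysis genes fell in 12 of 20 cases and rose in 1 (median -1.14), Eno2 at -6.04 and Slc2a3 at -2.61 against Hk2 at 1.88. None of the 20 oxidative phosphorylation genes was called with limma at the size required (median 0.06, or -0.25, -0.20 and -0.08 under the other scalings), although Atp5g1 was called after rescaling to a fixed sum (-1.02) and Cox8a under quantile normalization (-1.07). Interferon response genes rose in 3 of 15 cases and fell in 1 (median 0.09, or -0.08 after rescaling to a fixed sum), Ifit2 at 1.55 against Bst2 at -1.44, whose call ended without cortex replicate 1 (-1.46) and under quantile normalization (-0.82). Heat shock and unfolded protein genes rose in 2 of 18 cases, Hsp90b1 at 1.17, not called after rescaling to a fixed sum (0.86), and Sesn2 at 1.85, and fell in 2 (median -0.14, or 0.08 without genes listed at 0, a setting chosen after the data were seen), including Hspb1 at -1.95. A further lower call, for Ddit3, rested on a listed 0 in OPCs, against 13.9, 9.72 and 12.4 FPKM in cortex. Of 6 tested regional patterning genes 1 rose, Irx2 at 1.35 (median 0.15, or -0.13 after rescaling to a fixed sum). The counts adjusted over the list alone equalled those over all genes tested for each list in this comparison. Among 10000 random lists of like expression, the medians of the OPC, proliferation, cholesterol and ribosomal protein lists stood at the 100th percentile, and those of the pan-neuronal, synaptic, microglial, endothelial and astrocyte lists at percentile 0. With 1 OPC library, the test assumes that it varies as the cortex libraries do.

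The astrocyte library was compared with cortex in the same way. It combined high levels of several astrocyte genes with high levels of Olig1 and Olig2. Aldh1l1 stood at 301 FPKM against 23.4 ± 4.77 FPKM in cortex, 12.8-fold higher, and Slc1a3 at 412 FPKM, 3.12-fold higher. Gfap stood at 100 FPKM against 46.7 ± 6.04, 2.14-fold higher. Olig2 was at 266 FPKM, 14.1-fold above cortex, and Olig1 at 898 FPKM, 11.3-fold above, whereas Sox10 at 0.608 FPKM and Pdgfra at 1.16 FPKM were 26.6-fold and 17.6-fold below cortex. The EGF receptor gene Egfr rose to 42.5 FPKM from 3.92 ± 0.452, 10.8-fold.

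Of 13934 tested genes 6110 were called in astrocytes against cortex, 3133 higher and 2977 lower, with limma and the same Benjamini-Hochberg threshold and size, around a median log2 difference of 0.21. Of the lower calls 380 were for genes listed at 0 in astrocytes, and the lower count of each list includes 2 such genes at most. The larger direction changed with the setting here too, to 2421 higher and 3844 lower after rescaling to a fixed sum and to 2728 and 3161 under upper quartile scaling. The limma tests gave Benjamini-Hochberg adjusted p-values of 1.39e-04 for Olig2, 5.45e-04 for Aldh1l1 and 0.00539 for Gfap, each higher than in 3 of 3 cortex libraries. The Gfap difference, 1.09, was close to the required size, and its call ended without cortex replicate 2 (0.997) and under each of the other scalings (0.76, 0.92 and 0.97). The genes that rose most were Igfbp3, which binds insulin-like growth factors, at 7.10, the galectin gene Lgals1 at 6.86, the translation repressor gene Eif4ebp1 at 6.48, Ccnd1, encoding cyclin D1, at 6.03, Vim at 5.87 and the haem oxygenase gene Hmox1 at 5.65. Slc17a7 at -8.55, Nrgn at -8.43, Sst at -7.99, Camk2a at -7.84 and Sncb at -7.35 fell most, and Syn1, a synaptic vesicle gene, was listed at 0 in astrocytes and at 174, 183 and 180 FPKM in cortex.

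The astrocyte list was split, with 7 of its 20 genes higher, 9 lower and a median of -0.14, or 0.25 with exact symbols only, a setting chosen after the data were seen. Aldh1l1, Slc1a3, Sox9 at 2.41, the glycogen gene Ppp1r3c at 2.23, Gfap, Acsbg1 at 1.11 and Mlc1 at 1.09 rose, and the last pair was not called under any other scaling (0.77, 0.88 and 0.99 for Acsbg1, and 0.76, 0.89 and 0.97 for Mlc1). The connexin gene Gjb6 at -3.70, Slc1a2 at -3.66 and Aqp4 at -1.66 fell, and Aldoc, at 343 FPKM against 247 ± 33.2, was not called. On the reactive astrocyte list 14 of 19 genes rose and none fell (median 1.81), with Vim at 1954 FPKM and Nes at 177 FPKM. The OPC list had 10 of 20 genes lower and 5 higher (median -1.10). Those higher included Olig1 at 3.48, Olig2 at 3.75, Ptprz1 at 2.20 and Nkx2-2 at 1.01, a call that ended without cortex replicate 2 (0.91) or 3 (0.92) and under 2 scalings (0.83 and 0.91). Gpr17, a receptor of committed oligodendrocyte precursors, was listed at 0 in astrocytes and at 57.2, 43.5 and 45 FPKM in cortex. Of 19 mature oligodendrocyte genes 17 fell and 1 rose (median -2.84), Mbp at -4.35 and Enpp2 at -4.16 against the transferrin gene Trf at 1.45.

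All 20 synaptic vesicle genes fell (median -4.17), with Syp at -6.37 and Vamp2 at -3.93. The pan-neuronal list had 19 of 20 lower (median -3.75), the excitatory list 13 of 15 (median -3.72) and the inhibitory list 11 of 15 (median -3.16), including the peptide gene Npy at -6.78. Receptor genes fell in 15 of 19 cases (median -2.57), including Gabbr2 at -5.74 and Grin1 at -5.69. Microglial genes fell in 17 of 18 cases (median -3.43), with C1qc at -4.17, and 1, Cd14, rose by 1.25. Endothelial genes fell in 14 of 15 cases (median -2.57), with Cldn5 at -5.44, while the glucose transporter gene Slc2a1 was at 50.7 FPKM against 32.0 ± 2.06 and was not called. Pericyte genes fell in 6 of 11 cases and rose in 2 over all genes tested, and adjusted over the list alone 3 rose (median -1.08). Rgs5 was at -4.79, and the risers were Notch3 at 1.36 and the contractile gene Tagln at 3.46. Fibroblast genes fell in 6 of 14 cases and rose in 3 (median -0.76), Igf2 at -3.23 against Nupr1 at 3.99, Thbs1 at 1.65 and Pdgfrl at 1.49. Of 3 tested ependymal genes 2 rose (median 1.39), the ciliary regulator Foxj1 at 2.85 and Dynlrb2 at 1.39, the latter not called without cortex replicate 1 (1.24) or 3 (1.31), after rescaling to a fixed sum (1.59), at a pseudocount of 0.1 (2.31), or when confidence bounds were required not to meet. Hbb-bt fell by 1.70.

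Cell cycle genes rose in 22 of 23 cases (median 2.84), with Rrm2 at 4.02 and Top2a at 3.82. Ribosomal protein genes rose in 23 of 24 cases (median 1.89), Rps3 at 3.26 and Rpl7 at 2.26, and the call for Rplp1 at 1.03 ended without cortex replicate 2 (0.99) or 3 (0.90) and under each other scaling (0.69, 0.19 and 0.91), while Rps2, at 0.97, was called only without cortex replicate 1 (1.10). Cholesterol synthesis genes rose in 16 of 18 cases (median 1.91), including Insig1, a feedback regulator of the pathway, at 4.61. Neural stem cell genes rose in 12 of 17 cases (median 1.93), Nes at 5.13, and fell in 1, the immature neuron gene Dcx at -2.09. Receptor tyrosine kinase output genes rose in 11 of 15 cases (median 2.07), with Ccnd1 at 867 FPKM, Dusp4 at 4.07 and Etv5 at 2.86. On the PDGF and EGF receptor list 4 of 15 rose and 6 fell (median -0.50), the risers being Egfr at 3.15, the ligand genes Hbegf at 2.57 and Nrg1 at 1.24, and Erbb2 at 1.87, with Nrg3 at -3.42 and Pdgfb at -3.28 among those that fell.

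Matrix and adhesion genes rose in 11 of 19 cases and fell in 3 (median 1.44), with Tnc at 4.76 and Sparc at 1.99 against the basement membrane collagens Col4a1 at -1.06 and Col4a2 at -2.09 and Col6a2 at -1.20. The Notch list had 9 of 15 genes higher and 4 lower (median 1.28), with Notch1 at 3.02 and Lfng at 2.01 against Jag2 at -2.88, Nrarp at -2.57, Hey1 at -1.24 and Hey2 at -1.12, a call that ended under quantile normalization (-0.54). Stress genes of the heat shock and unfolded protein list rose in 10 of 18 cases and fell in 1 (median 1.11), Trib3 at 5.31, Sesn2 at 4.01 and the transcription factor gene Atf4 at 2.78 against the chaperone gene Hsph1 at -1.11. Interferon response genes rose in 10 of 15 cases (median 1.11), with Bst2 at 2.46 and Tap1 at 2.29. Immediate early genes fell in 13 of 17 cases and rose in 2 (median -1.80), Egr3 at -4.44 against Jun at 2.19 and Btg2 at 1.82. The Btg2 call ended when no filter on low values was used. Glycolysis genes fell in 4 of 20 cases and rose in 3 (median 0.07, or -0.28, -0.29 and -0.05 under the other scalings), Eno2 at -3.78 against Hk2 at 2.58, Pkm at 2.08 and Pgk1 at 1.34, a call that ended under quantile normalization (0.89) and after rescaling to a fixed sum (0.999). No oxidative phosphorylation gene of 20 was called with limma at the size required (median 0.31, or -0.03 after rescaling to a fixed sum and -0.08 under quantile normalization), and Atp5b was at 926 FPKM against 548 ± 16.0. Of 6 patterning genes 2 rose (median 0.66), the forebrain genes Emx2 at 3.57 and Otx1 at 1.13, the latter not called after rescaling to a fixed sum (0.97). Except for the pericyte list, the counts adjusted over the list alone equalled those over all genes tested. Among 10000 random lists of like expression, the medians of the reactive astrocyte, matrix, receptor kinase output and proliferation lists stood at the 100th percentile, those of the neuronal and mature oligodendrocyte lists at percentile 0, and that of the astrocyte list at 7.24. Again the lone library was assumed to vary as the cortex libraries do.

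**Figure D2:**
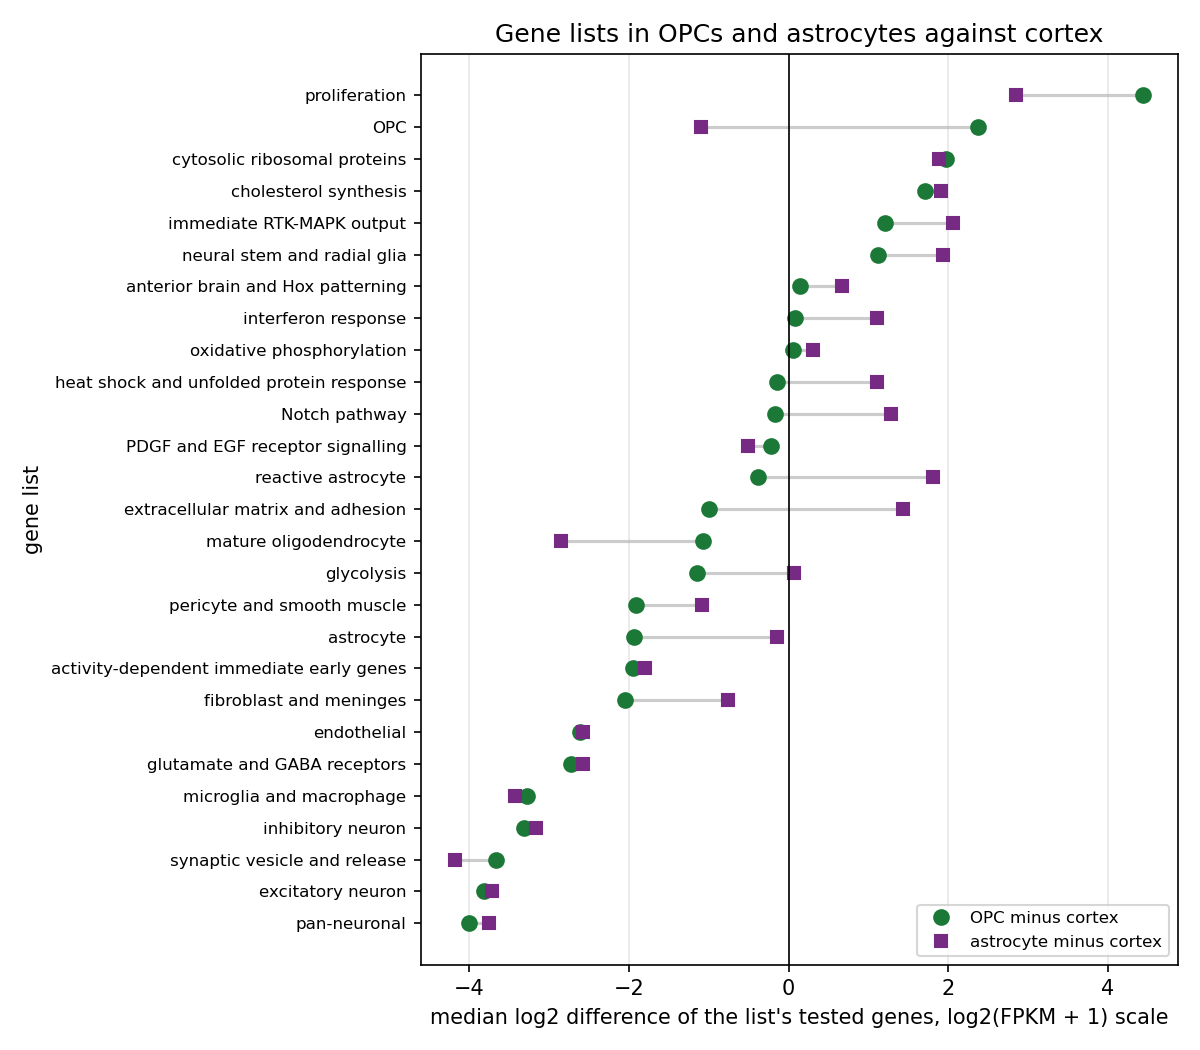
Median log2 difference of the tested genes of each list with at least 5 of them, on the scale of log2 of FPKM plus 1, in OPCs (circles) and astrocytes (squares) against the mean of the 3 cortex libraries. Neuronal, microglial and endothelial lists lie below 0 in both, proliferation and ribosomal protein lists lie above 0 in both, and the OPC list lies at 2.37 in OPCs and at -1.10 in astrocytes.

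The comparisons with cortex shared many genes. Both cell types were called higher for 1675 genes, among them Olig1, Olig2, Sox9, Vim, Nes, Ccnd1 and Mki67, and lower for 2302, among them Rbfox3, Slc17a7, Syp, Aqp4 and Pdgfb. Opposite calls were made for 225 genes, 72 higher in OPCs and lower in astrocytes, such as Pdgfra and Sox10, and 153 the reverse, such as Aldh1l1 and Slc1a3. If the called lists were independent, 660 shared higher and 680 shared lower genes would be expected. Both comparisons used the same 3 cortex libraries. In 100 simulations of unchanged cells that shared them, the same-direction calls numbered 0.13 on average and 1 at most, against 3977 in the data. The simulated cells varied as the cortex libraries do and no gene was changed in them, so few calls of any kind could arise. The simulations therefore show only that sharing those libraries makes few calls by itself. How far the sharing raises the overlap among genes that do differ cannot be read from them. They do not address the different making of cell and cortex files, which both comparisons also share. Pearson's r of the log2 differences, across genes and not across independent replicates, was 0.723 in the data and 0.251 on average in the simulations.

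The OPC and astrocyte libraries were set against each other to show which genes tell the glial types apart. Of 13934 genes 1170 differed by at least 2 on the log2 scale, 445 higher in OPCs and 725 higher in astrocytes. With 1 library per group these differences had no replicate check and no p-value. Of these genes 120 and 128 were listed at 0 in astrocytes and in OPCs. Pdgfra was 356-fold and Sox10 456-fold higher in OPCs as ratios of listed FPKM, with log2 differences of 7.58 and 7.43 after 1 was added, whereas Aldh1l1 was 74.0-fold and Egfr 13.3-fold higher in astrocytes. Cspg4 was also higher in OPCs, at a log2 difference of 3.26, as was Mbp at 2.5, while Olig2 at 0.46, Olig1 at 0.29, Sox9 at -0.21, Pdgfb at -0.51 and Rbfox3 at -0.06 were under the size rule. Slc1a3 at -3.01, Gfap at -2.49 and Aqp4 at -2.12 were higher in astrocytes, although Aqp4 fell under the rule with quantile normalization (-1.81).

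Besides Pdgfra and Sox10, the genes with the largest differences on the OPC side included some listed at 0 in astrocytes, namely Gpr17 at 262 FPKM in OPCs, the mitochondrial ribosomal genes Mrpl18 at 76.9 and Mrps26 at 51.2, and the replication factor gene Rfc4 at 54.1. On the astrocyte side they were the annexin gene Anxa3 at -7.60, osteopontin (Spp1) at -7.05, Thy1 at -6.99 and the collagen chaperone gene Serpinh1 at -6.83. Tmem256 at 146 FPKM and the respiratory complex gene Ndufb10 at 138 FPKM in astrocytes were listed at 0 in OPCs. Whether these are true zeros is not known, so no single gene listed at 0 is taken to tell the cell types apart. The list counts below do include such genes. Without them, 10 OPC genes were higher in OPCs, and 6 reactive astrocyte and 5 stress genes were higher in astrocytes.

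By list, 11 of 20 OPC genes were higher in OPCs and none in astrocytes (median 2.70), and 10 of 19 mature oligodendrocyte genes were higher in OPCs and 1 lower (median 2.02). Among the latter, Enpp2 differed by 4.84, Cldn11 by 4.61, Cnp by 2.04 and Trf by -3.80. Of 20 astrocyte genes 11 were higher in astrocytes (median -2.13), Gja1 at -5.14, and 1 in OPCs, S100b at 2.39. Matrix genes were higher in astrocytes in 8 of 19 cases (median -1.40), with Sparc at -5.0 and Lgals1 at -4.43, and reactive astrocyte genes in 8 of 19 (median -1.73), with the chemokine gene Cxcl10 at -3.71. Receptor kinase output genes were higher in astrocytes in 4 of 15 cases (median -0.88), with Dusp4 at -4.42 and Epha2 at -2.76, and stress genes in 6 of 18 (median -1.38), with Trib3 at -4.84. Proliferation genes had a median of 1.52 and passed the rule in 1 of 23 cases, Mcm5 at 2.28, which was lost when the confidence bounds of the libraries were required not to meet. The Notch ligand gene Dll3 differed by 3.82, Tgfa by 4.17, Erbb4 by 3.64, Hbegf by -3.25 and Emx2 by -2.82. No ribosomal protein or oxidative phosphorylation gene passed the rule (medians 0.06 and -0.40), nor did any microglial gene (median -0.11, or 0.05 under quantile normalization). The microglial gene Cd14 passed it after rescaling to a fixed sum (-2.11) and at a pseudocount of 0.1 (-2.96).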

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

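The tests on Olig1 and Olig2 and on genes listed at 0 were chosen after the results were seen, and the tests on ribosomal protein genes were set out before the values they measure were seen. Groups of 3 libraries or fewer were not examined for a single deviating sample.

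Olig1 and Olig2 were high in the astrocyte library, at 81.6% and 72.7% of their OPC levels, although Sox10 was at 0.219% and Pdgfra at 0.281%. OPCs mixed into the astrocytes would bring the other OPC genes at a like percent, but the median of 15 of them was 8.10%, with 7 under 5% and 11 under 36.4%, which is 50% of the value of Olig2. A first form of this test also required the upper quartile to lie under that bound; it was 47.8%, so that condition was not met, and it was dropped because astrocytes may express some of these genes themselves. Scaling of the library could not account for the difference either, since the lowest log2 difference of the pair from cortex over 4 scalings was 2.82. Expression of Olig1 and Olig2 by the astrocytes, a property of how the cells were obtained or grown, and the different making of cell and cortex files stay open as untested hypotheses.

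Ribosomal protein genes were higher in both cell libraries, with medians of 1.98 and 1.89. Short transcripts do not account for this alone, because the upper end of the central 95% of random lists matched on length and expression was 1.35 at the most. Those random lists had medians of 0.48 in OPCs and 0.71 in astrocytes, so a part may go with length and expression. Oxidative phosphorylation genes of similar median length had medians of 0.06 and 0.31, but 1 list cannot separate length from its own difference from cortex. The lowest ribosomal median over 4 scalings and both libraries was 1.23. The rise was not confined to genes with many processed pseudogene copies. The 12 genes with the fewest had a median of 1.84 in OPCs and 1.88 in astrocytes, against 2.11 and 1.90 for the others. Some of those 12 had up to 3 copies, so reads shared with pseudogenes are not excluded as a part of it. A difference between cells and tissue and the different making of their files may each contribute, and the design does not separate them.

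Of the tested genes, 21 were listed at 0 in OPCs and 15 in astrocytes while the other cell library and the cortex mean held 10 FPKM or more. These 36 genes were compared with genes above 0 that also held 10 FPKM or more in the other cell library and the cortex mean. That gave 9218 entries, because a gene could enter once for each cell library. Assembled unnamed loci overlapped 30.6% of the 36 genes (exact 95% interval 16.3 to 48.1), against 13.8% of the 9218 entries. Loss of reads to such loci is a candidate explanation for the 11 overlapping genes but not for the other 25. Another named gene overlapped 66.7% of the 36 genes (49.0 to 81.4), against 20.4% of the 9218 entries. Assignment of reads to an overlapping named gene is a candidate explanation for those 24 genes but not for the other 12. The 9 genes that overlap neither were left without a tested source, and 8 overlap both. No biological explanation was tested.

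Of the genes that the naming rule takes, 30 were called in opposite directions against cortex, of which 24 were above 0 in both cell libraries, and the difference between the cell types was not tested, with 1 library each. Those higher in OPCs were Pdgfra (log2 difference between OPCs and astrocytes 7.58), Sox10 (7.43), Gal3st1 (4.32), Tgfa (4.17), Erbb4 (3.64) and Myrf (3.20). Those higher in astrocytes included Anxa3 (-7.60), Spp1 (-7.05), Serpinh1 (-6.83), Nupr1 (-5.94), Aldh1l1 (-5.90), Sparc (-5.0), Mlc1 (-4.29), Bst2 (-3.89) and Trf (-3.80). The other 9 were Ppp1r3c (-3.52), Notch3 (-3.36), Acsbg1 (-3.16), Slc1a3 (-3.01), Thbs1 (-2.96), Pdgfrl (-2.53), Gfap (-2.49), Dusp6 (-2.46) and Hes1 (-2.42). Under other scalings the calls of Gfap, Mlc1 and Acsbg1 in astrocytes and of Gal3st1, Myrf and Bst2 in OPCs ended.

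Signal appeared in loci that no comparison used. Unnamed loci with at least 1 FPKM numbered 11617 in OPCs and 8116 in astrocytes, against 0 in each cortex file, which lists annotated genes only. Loci on the mitochondrial chromosome reached 1016 FPKM in OPCs and 1186 FPKM in astrocytes, and the cortex files list none. Unnamed loci held 80.2% and 68.7% of the summed FPKM. Only 208 and 167 loci, those spanning under 100 bases, held 86.2% and 88.7% of the unnamed part. Since FPKM is per kilobase, very short loci weigh heavily in such sums, and these percents are not shares of reads.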

How the results depend on the processing

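The alternatives for joined names, small RNA genes, coordinates, values of 0 and estimate status were chosen after the data were seen. Of 350 results for named genes, 266 stayed on the same side of their rule under every alternative run for them, and none reversed. Across all alternatives these gave 125 lost and 26 gained calls, many of them with the stricter test or size rule. Calls lost without a filter were those of Bst2, Btg2, Dusp5 and Rps2 in OPCs and of Btg2, Dynlrb2, Mlc1, Nkx2-2 and Rplp1 in astrocytes. Of 87 list medians, 17 changed sign under at least 1 alternative, 16 of them inside the central 95% of random lists in the main analysis. The other was the matrix and adhesion median in OPCs against cortex, which changed from -0.99 to 0.17 when only genes with the same coordinates in all files were kept; fewer genes were tested there. The treat test of limma against a log2 difference of 1, stricter by construction, called 4009 genes in OPCs against cortex and 2516 in the same direction in both cell types. Between OPCs and astrocytes, 2059 genes stood apart at a pseudocount of 0.1, and 3492 and 510 with size rules of 1 and 3. The lowest r between cortex libraries was 0.906 at a pseudocount of 0.1, 0.971 with no filter and 0.921 with the same coordinates. Leaving out the small RNA genes raised the lowest r from 0.936 to 0.990, so those genes lowered it in the main analysis. Why they differed between the cortex libraries was not tested. Without 1 cortex library, calls ranged from 6101 to 6142 in OPCs, from 6067 to 6180 in astrocytes and from 3943 to 4008 in both.

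Scaling moved the balance of directions more than the totals. After rescaling to a fixed sum, the median log2 difference of all genes was -0.14 in OPCs and -0.08 in astrocytes, and calls were 2309 higher and 4173 lower in OPCs, against 2936 and 3184, and 2421 higher and 3844 lower in astrocytes, against 3133 and 2977. Other settings gave the OPC calls a higher majority, with 3093 higher and 2723 lower under quantile normalization, 2240 and 2006 at a mean of at least 5 FPKM, and 2855 and 2701 without genes listed at 0. The astrocyte calls had a lower majority under upper quartile scaling (2728 and 3161), with the treat test (1893 and 2261) and with the same coordinates (2193 and 2380). After rescaling to a fixed sum, genes called the same way split into 1198 higher and 3031 lower. Without genes listed at 0, 5556 genes were called in OPCs and 5551 in astrocytes. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. No comparison had 3 libraries in each group, so the libraries were not regrouped. With depth unknown as counts, a value of 0 has no stated detection limit.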

Other observations

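The genes in these paragraphs were chosen after their values were seen, and no explanation was tested. Several imprinted genes were looked at. H19 was at 174 FPKM in OPCs and 7.78 in astrocytes, Dlk1, a membrane-bound Notch ligand relative, at 15.1 and 0.205, and the growth inhibitor gene Cdkn1c at 11.2 and 0.578. Nnat was at 380.0 and 47.4 FPKM and Peg3 at 24.3 and 3.38. Mest, at 14.3 FPKM in OPCs and 111 in astrocytes, and Grb10, at 12.5 and 53.5, were higher in astrocytes. Igf2 was low in both, at 4.87 and 5.20 FPKM against 57.3 ± 5.22 (SD, n = 3) in cortex, and Meg3, which shares its locus with small RNA genes, was at 28.7 and 8.85 against 312 ± 88.1.

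The forebrain transcription factor gene Lhx2 was at 16.1 FPKM in OPCs, 39.5 in astrocytes and 25.7 ± 5.80 in cortex. Sex-linked genes separated the cortex libraries. Xist, transcribed from the inactive X chromosome, was at 33.1 FPKM in cortex replicate 1 and at 0.149 and 0.245 in replicates 2 and 3. The Y-linked gene Ddx3y was at 0.00559, 9.88 and 9.93 FPKM in those libraries, and Eif2s3y was listed at 0 in replicate 1 and at 18.6 and 20.1 in the others. The OPC library held both, with Xist at 91.7 and Eif2s3y at 37.9 FPKM, and so did the astrocyte library, with 59.8 and 17.8 FPKM.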
